A study of Mus musculus with 2 samples.

How the data were processed

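Crypts of the small intestine were prepared from C57BL/6 mice kept under specific pathogen-free conditions, per the labels. A 5 cm piece of distal ileum was opened, freed of villi by scraping and digested in 0.1% collagenase for 20 min at 37 °C, and digestion was stopped when about 70% of crypts had come loose, per the labels' protocols. Total RNA was amplified to biotin-labelled cRNA and hybridised to Affymetrix arrays, per the labels' protocols. Groups were taken from the labels, with 1 array for Cnep1r1 deletion and 1 for wild type.

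The values deposited by the authors are on a log scale, taken here as log2, with 1 value per transcript cluster (the array's unit for a gene's probes) rounded to 2 decimals. The submitters' processing notes name affy 1.46.1 with no role. Summarization, background correction, normalization and the log base are not given in the sources used here. The 2 columns had close distributions, with medians of 4.98 and 4.94 and maxima of 19.89 and 19.88. Values above 16, the log2 of the largest 16-bit scanner reading, occurred 305 times on the deletion-labelled array and 280 times on the wild-type array, and whether another log base, the summarization or another step put them there was not tested. Scanner files were not used here, so signal over background is unknown for single probes.

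Of 22206 transcript clusters, 19572 had 1 gene symbol in the platform annotation used. The other 2634 had none or several, not counted apart, and were left out. All 19505 gene IDs matched the RefSeq gene table of assembly GRCm38.p6, which served for symbols and for the order of neighbouring genes only, since no build is named in the sources used here, and no coordinates are given. For 55 genes with more than 1 cluster, the cluster with the highest mean was used. A gene was kept when its value reached its array's own median over named genes (5.19 and 5.16) on at least 1 array, which left 10007 genes and set aside 9498. The values were not normalized again. Differences are deletion-labelled minus wild-type log2 values, and a size of 1, or 2-fold, was set before the data were examined.

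Also fixed before the data were examined were 34 gene lists (5 primary and 29 others), the rule for named genes and the alternatives. A list was described by the median difference of its kept members and by that median's percentile among 10000 random lists of the same size drawn to match its members over 20 bins of mean expression. A list is said to stand apart below percentile 2.5 or above percentile 97.5. Percentiles are quoted for lists with at least 5 kept members, a limit set after the values were seen. Counts of lists standing apart include mast cells and smooth muscle, with 4 and 3 kept members. Several fixed members, such as Olfm4 and Cd74, had no named cluster here, and lists overlap in Sox9, Axin2, Lgr5, Chga, Zg16 and Atf3 among others. The tuft cell gene Irag2 was read under its older symbol Lrmp, an alias added by hand after the values were seen. A further 11 lists were added after the values were seen and are reported as such.

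The rule for named genes took Cnep1r1, the 15 highest and 15 lowest kept genes (predicted genes, receptor segments and olfactory genes aside), the 4 largest differences in each primary list, the 3 largest in the direction of the median in each other list that stood apart, and sex-linked and substrain genes. Of the last, Xist, Ddx3y and Nnt had no named cluster here. Other genes named in the text, such as Lyz1, Mmp7, Itln1, the Reg3 genes, Xbp1, Agr2, Fzd5, Ctdnep1, Muc2, Kit, Zg16 and Amy2a5, were chosen after their values were seen.

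Each gene and list value was recomputed with the medians set equal, quantile normalization, loess of the difference on the mean (span 0.7), no filter, a filter on both arrays, the mean over clusters, genes with 1 cluster, 10 bins and random lists without matching, and counts of genes also at 1.5-fold and 3-fold. Leaving out the Defa genes was also planned. Counting identical granule values once and leaving out Zg16 were added after the values were seen. The calculation was tested on simulated arrays of 10010 kept genes. There, 90% of 100 genes given a log2 difference of 1.5 and 100% of 100 given 3 passed the 2-fold size, along with 109 of 9810 genes given none. Of 200 simulated lists with no shift 4 stood apart, and of 20 lists shifted by 0.5 all 20 did. The simulated noise was independent between genes, with its size taken from the differences of these 2 arrays. These rates therefore do not cover lists whose members vary together. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1 were used.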

Results

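Gene expression was measured in small-intestinal crypts of C57BL/6 mice, the glands below the villi that house stem cells and Paneth cells. Per the labels, villi were scraped off a distal ileum section and crypts were released with collagenase. Biotin-labelled cRNA was hybridised to Affymetrix arrays, 1 array for each of 2 groups: Cnep1r1 deletion (Cnep1r1ΔIEC in the labels) and wild type. The labels do not say how many animals stand behind each array. Cnep1r1 encodes a regulatory subunit of the membrane-bound phosphatase CTDNEP1, which acts on lipins, the enzymes that make diacylglycerol from phosphatidic acid. The series title places the question in the packaging and formation of dense core vesicles in Paneth cells, the crypt cells that secrete antimicrobial peptides. Each array gave 22206 log2 values, with a median of 4.98 on the deletion array and 4.94 on the wild-type array. With 1 array per group there was no replicate error, no test and no replicate check for any difference, so "higher" and "lower" describe these 2 arrays, and the number of arrays limits the precision.

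Cnep1r1 itself had a log2 value of 10.43 on the array labelled as the deletion and 10.70 on the wild-type array, a difference of -0.27 and a ratio of 0.829. Among the 10007 genes kept for comparison, 47.7% differed by at least that much in size. Where the probes of Cnep1r1 lie relative to the deleted part of the gene is not given in the sources used here, so this value does not settle the label, and the array is called the deletion-labelled array.

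Transcripts of Paneth cell granule products were higher on the deletion-labelled array, at a median of 4.47-fold over 31 kept genes. They included Lyz1, the granule lysozyme, Mmp7, the protease that activates α-defensins, and 21 α-defensin (Defa) genes. Pancreatic digestive enzyme genes were higher too, at a median of 5.26-fold over 14 genes, as were the gasdermin C genes and, by smaller amounts, stem cell and enteroendocrine markers. Genes lower on the deletion-labelled array included MHC class II genes, interferon-inducible GTPases, T cell markers, several absorptive enterocyte markers and a set of stomach genes led by Gkn2 and Tff1. Genes of ER stress, glycerolipid synthesis, the cell cycle and ribosomes showed list medians close to 0. Folds take the deposited log scale as base 2, an assumption made from the values and the named software that no source used here states, and why some values lie above 16, the log2 of the largest 16-bit reading, is not known.

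**Figure D1:**
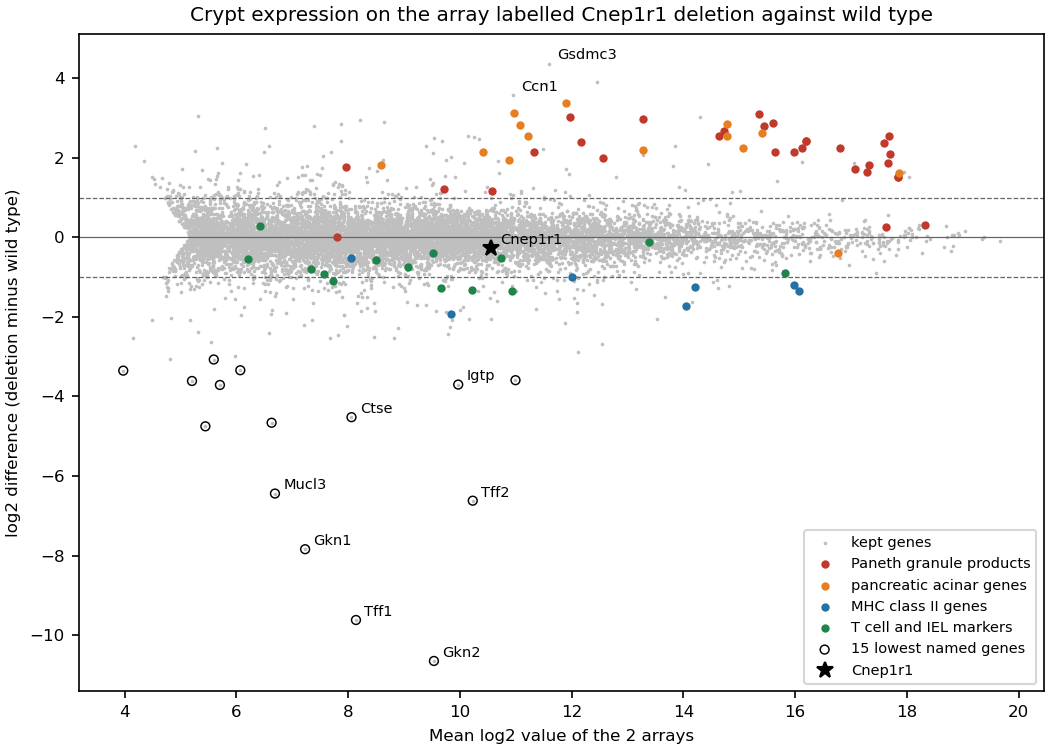
Log2 difference (deletion-labelled minus wild-type array) against the mean log2 value of the 2 arrays for 10007 kept genes, each a point. Coloured points mark members of 4 gene lists, open circles the 15 lowest named genes, the star Cnep1r1 at -0.27, and dashed lines a log2 difference of 1 and -1; Paneth granule and pancreatic genes lie mostly above the upper line and Gkn2 lies lowest at -10.65.

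Across the kept genes the 2 arrays were close, with a median log2 difference of -0.01, and 83.4% of genes lay within 1.5-fold. A 2-fold size or more separated the arrays for 246 genes higher and 228 genes lower on the deletion-labelled array, leaving 9533 in between. Among 22 kept genes read by several transcript clusters, the differences of the clusters lay a median of 0.36 apart and at most 1.19. Of the 34 gene lists fixed before the data were examined, 13 had medians above and 5 below the central 95% of 10000 random lists matched for size and mean expression, where chance at 5% would give 1.7. That range describes these arrays only, and it is too narrow for lists whose members vary together.

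The Paneth granule list had 28 of 31 kept members higher by 2-fold or more and none lower by that size. Its median log2 difference was 2.16, and 0 of 10000 random lists had a median as high. The 4 members with the largest differences were Defa43 (16.91 on the deletion-labelled array against 13.80 on the wild-type array), Defa26 (13.48 against 10.46), Defa40 (14.76 against 11.79) and Ang4 (17.03 against 14.16), a secreted ribonuclease with microbicidal activity. Chosen after their values were seen, Lyz1 stood at 18.60 against 16.74, Mmp7 at 13.36 against 10.96, and Itln1, a lectin that binds microbial sugars, at 18.24 against 16.42. The lectins Reg3b (18.48 against 18.18) and Reg3g (17.75 against 17.49), made by several epithelial cell types, differed least together with Reg3a, at 0.01. All 21 kept Defa genes of the list were higher by 2-fold or more, although near-identical sequences can share probes and 2 pairs of granule genes carried identical values. Without the Defa genes, 10 members remained, 7 of them higher by 2-fold or more, with a median of 1.93.

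Paneth cell regulators and markers outside the granule differed less. Their median was 0.32 over 17 kept genes (percentile 99.7 of the random lists), with 4 members higher by 2-fold or more and none lower. With no filter on dim genes that median was 0.175 (percentile 97.8), and 0.20 (percentile 97.7) where both arrays had to pass the filter. The 4 were Habp2 (9.68 against 6.73), which encodes a secreted serine protease, the stress-inducible chromatin protein gene Nupr1 (10.89 against 8.46), Thbs1 (5.26 against 3.99) and Sox9 (10.21 against 9.09), a transcription factor that Paneth cells require. The secretory transcription factor Xbp1 (-0.14), the disulfide isomerase Agr2 (-0.26) and the Wnt receptor Fzd5 (-0.34) had differences below 0. Xbp1 is also in the ER stress list and Agr2 in the goblet cell list, so neither is particular to Paneth cells.

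**Figure D2:**
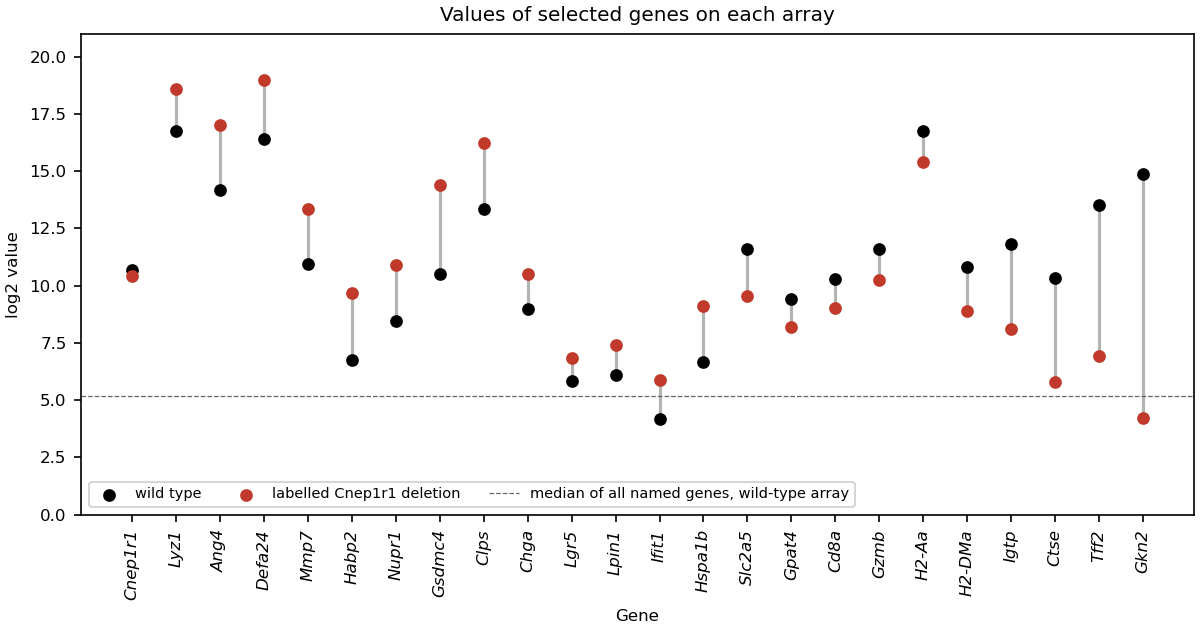
Log2 values of 24 selected genes on the wild-type array (black) and the deletion-labelled array (red), 1 point per array, with the wild-type median over named genes as a dashed line; some genes were chosen after their values were seen. Lyz1 stood at 18.60 on the deletion-labelled array against 16.74, Cnep1r1 at 10.43 against 10.70, and Gkn2 at 4.21 against 14.86.

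Dense core vesicle and secretory granule machinery, the group nearest the series title, had a median of 0.03 over 35 kept genes (percentile 74.4), inside the range of random lists. Of these, 4 were higher by 2-fold or more, none was lower and 31 lay in between. The 4 were the vesicle membrane protein gene Ptprn2 (7.20 against 5.62), the granins Chga (10.51 against 8.96) and Scg2 (7.07 against 5.53), and Ica1 (8.54 against 7.25), genes also active in neuroendocrine cells. With no filter on dim genes the list median was 0.12 and lay above the random range, at percentile 97.6. Enteroendocrine markers, another list that shares Chga and Chgb with this one, were above 0 for 16 of 16 kept genes, with a median of 0.75 (no random list of 10000 as high). Reg4 (14.72 against 12.92), Chga and the neurotensin gene Nts (6.35 against 5.32) led it.

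Genes of ER stress and the unfolded protein response had a median of -0.03 over 26 kept genes (percentile 39.6), with 1 higher by 2-fold or more and none lower. Atf3, a stress-induced transcription factor that is also in the dissociation and immediate early list (median 0.66), stood at 12.85 against 11.78. Differences for the ER chaperone and degradation genes Sdf2l1, Sel1l and Pdia3 were -0.54, 0.51 and -0.46. The list of glycerolipid and phospholipid synthesis with the lipin phosphatase partners had a median of -0.10 over 31 kept genes (percentile 12.5). Lpin1, a phosphatidic acid phosphatase of the lipin family, was higher (7.39 against 6.08), as was the choline kinase gene Chka by less than 2-fold (8.07 against 7.28). Gpat4, an ER acyltransferase of the first step of glycerolipid synthesis, was lower (8.18 against 9.43), and the lipid droplet coat gene Plin3 stood at 10.32 against 11.17. Ctdnep1, the catalytic partner of Cnep1r1, stood at 8.99 against 9.28.

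Sterol and fatty acid synthesis genes, the targets of SREBP, had 19 of 23 kept members below 0 and a median of -0.18, at percentile 2.46 and so on the edge of the random range. Scd1, the stearoyl-CoA desaturase gene, was lower by 2-fold or more (9.18 against 10.39), while Insig1 and the sterol dehydrogenase gene Nsdhl differed by -0.67 and -0.66. This list lay inside the random range under 7 of the alternative settings.

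Markers of crypt base stem cells were above 0 for all 11 kept genes, with a median of 0.81, and no random list of 10000 reached it. Slc12a2 (15.59 against 14.42), the Wnt target Axin2 (10.21 against 9.10) and the stem cell receptor Lgr5 (6.85 against 5.85) were the 3 at 2-fold or more. Wnt targets shared the kept genes Axin2, Lgr5 and Znrf3 with the stem cell list, and Sox9 and Ephb3 with the Paneth regulators. Their median was 0.86 over 7 kept genes, the value of Znrf3, or 0.285 (percentile 98.0) with no filter on dim genes. Myc (0.18) and Cd44 (0.0), which are in neither of those lists, lay near 0. Cell cycle genes were 28 of 28 within 2-fold, with a median of 0.07 (percentile 88.6). Absorptive enterocyte markers had 6 of 22 kept members lower by 2-fold or more and none higher, with a median of -0.34. They were led by the fructose transporter gene Slc2a5 (9.53 against 11.58), the trehalase gene Treh (7.43 against 8.91) and Cyp3a11 (6.98 against 8.29). Levels of these markers ran from 6.08 (Mep1a) to 17.02 (Fabp2) on the deletion-labelled array and from 5.11 (Mep1a) to 17.89 (Anpep) on the wild-type array. Enterocyte transcripts thus remained on both arrays after the scraping named in the labels. Goblet cell markers had a median of 0.26 over 14 kept genes (percentile 99.6), with Ccl6 (12.76 against 11.05), Ccl9 (12.49 against 11.45) and Spink4 (17.31 against 16.38) highest and the main mucin gene Muc2 at 16.21 against 16.26. Tuft cell markers had a median of 0.41 over 8 kept genes (percentile 98.9), with Gfi1b at 0.82, Alox5ap at 0.76 and Rgs13 at 0.60, and they lay inside the random range with no filter on dim genes (median 0.21).

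**Figure D3:**
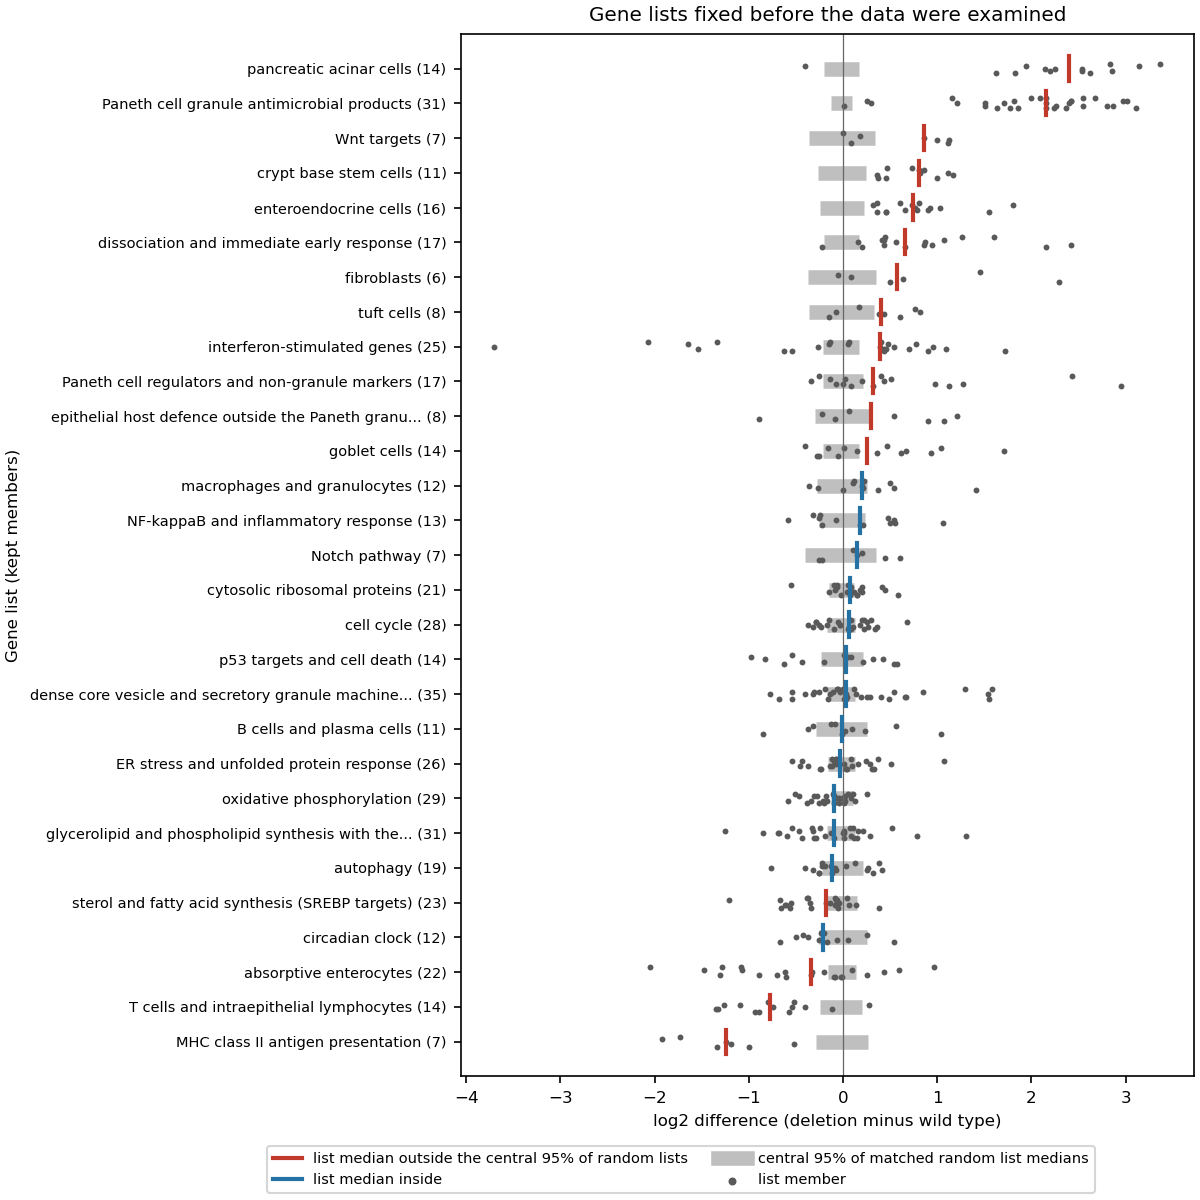
Log2 difference (deletion-labelled minus wild-type array) for the 29 fixed gene lists with 5 or more kept members; points are genes, vertical marks list medians (red outside, blue inside the central 95% of matched random lists, drawn as grey bars). Medians ran from 2.40 for pancreatic acinar genes to -1.24 for MHC class II genes.

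All 7 kept MHC class II genes were lower on the deletion-labelled array, 6 of them by 2-fold or more, with a median of -1.24 that no random list of 10000 reached. H2-DMa (8.88 against 10.80) and H2-DMb1 (13.18 against 14.91), which load peptides, and the peptide-presenting chain gene H2-Aa (15.40 against 16.74) were lowest. Interferon-stimulated genes went both ways. Their list median was 0.39 over 25 kept genes (percentile 99.99), with 2 higher and 5 lower by 2-fold or more, and it was 0.06, inside the random range, when both arrays had to pass the filter on dim genes, and 0.21 with no filter. Split by family after the values were seen, 5 of 6 immunity-related GTPase and guanylate-binding protein genes were lower by 2-fold or more, with Igtp at 8.12 against 11.82. The 7 IFIT, OAS and MX genes were all above 0, led by Ifit1 (5.89 against 4.17) and Oasl2 (11.45 against 10.36), with Ifit3 at 7.99 against 7.03. Tgtp2, another interferon-inducible GTPase gene, stood at 9.20 against 12.79.

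T cell and intraepithelial lymphocyte markers were below 0 for 13 of 14 kept genes, with a median of -0.77 and no random list of 10000 as low. The granzyme gene Gzmb (10.26 against 11.61), the T cell receptor complex gene Cd3e (9.56 against 10.89) and the co-receptor gene Cd8a (9.03 against 10.29) were among 4 at 2-fold or more. Of the mast cell list, 4 genes were kept, and Cpa3 (4.66 against 5.88), Mcpt1 (8.83 against 9.98) and Mcpt2 (4.88 against 5.95), all encoding mast cell proteases, were lower, while the receptor gene Kit stood at 7.64 against 7.26. The mast cell median was -1.11, or -0.33 with no filter on dim genes, and -0.39, inside the random range, where both arrays had to pass the filter. Macrophage and granulocyte markers had a median of 0.21 over 12 genes (percentile 95.1) and B and plasma cell markers -0.01 over 11 (percentile 54.7). Lists for inflammatory NF-κB targets (0.18, 13 genes, percentile 94.6) and host defence outside the Paneth granule (0.30, 8 genes, percentile 97.9) lay near the upper edge of the random range. In the latter, Lcn2 (7.85 against 6.64), Cyba (11.48 against 10.41) and Duoxa2 (9.10 against 8.20) were higher, but with no filter on dim genes both medians turned and lay inside the random range, at -0.03 for NF-κB targets (percentile 39.9) and -0.04 for host defence.

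Pancreatic acinar genes, fixed as a list of another tissue that could enter the preparation, had 13 of 14 kept members higher by 2-fold or more, with a median of 2.40 and no random list of 10000 as high. Pnliprp1 (13.58 against 10.21), Cela1 (12.53 against 9.39) and Clps (16.21 against 13.35), which encode a lipase-related protein, an elastase and colipase, led it. The exception was Zg16 (-0.40), which goblet cells also make, and the list median without it was 2.54. The amylase gene Amy2a5, chosen after its values were seen, stood at 18.66 against 17.04, a high level on both arrays.

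Stromal lists held few kept genes. Among fibroblast markers, with 6 kept and a median of 0.57 (percentile 99.8), the matrix genes Sparc (7.73 against 5.44), Dpt (6.75 against 5.30) and Dcn (12.84 against 12.20) were highest, and the median was 0.25, inside the random range, with no filter on dim genes. Smooth muscle had 3 kept genes with a median of 0.98, namely Acta2 at 1.17, Myh11 at 0.98 and Smtn at -0.60, and the median was 0.29 where both arrays had to pass the filter and 0.535 with no filter. Endothelium had 2 kept genes (median -0.39, or 0.07 with no filter), enteric neurons and glia 1 (0.06, or 0.44 with no filter) and erythroid cells 1 (-0.27, or -0.095 with no filter). Genes of the immediate early and dissociation response, which tissue handling induces, had a median of 0.66 over 17 kept genes, with no random list of 10000 as high. The heat shock genes Hspa1b (9.09 against 6.67) and Hspa1a (8.77 against 6.61) and the nuclear receptor gene Nr4a1 (8.25 against 6.65) led that list.

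Other fixed lists had medians inside the random range. Autophagy genes had a median of -0.12 over 19 genes, Notch pathway genes 0.15 over 7, p53 and cell death genes 0.03 over 14, and circadian clock genes -0.22 over 12 (percentile 5.18). Oxidative phosphorylation genes had a median of -0.10 over 29 and cytosolic ribosomal protein genes 0.07 over 21, or -0.095 with quantile normalization. The Y-linked genes Eif2s3y (11.59 against 9.11), Kdm5d (8.09 against 7.47) and Uty (10.28 against 10.35) gave signal on both arrays.

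The 15 highest genes by difference were led by the gasdermin C genes Gsdmc3 (13.78 against 9.41), Gsdmc4 (14.41 against 10.50) and Gsdmc2 (13.47 against 9.60), members of a family of pore-forming proteins. Next came Ccn1, a secreted matrix signalling protein gene (12.74 against 9.17). The 15 also held the endothelin precursor gene Edn1, at 6.83 against 3.78 and so dim on the wild-type array, and the pancreatic protease genes Ctrl (15.82 against 12.79) and Cela2a (12.49 against 9.66). The remaining 8 were Pnliprp1, Cela1, Clps, Defa43, Defa26, Defa40, Ang4 and Habp2.

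Stomach genes filled much of the 15 lowest. Gkn2 stood at 4.21 on the deletion-labelled array against 14.86, Gkn1 at 3.31 against 11.15, Tff1 at 3.33 against 12.95 and Tff2 at 6.92 against 13.54, all products of gastric mucous cells. Ctse, an aspartic protease gene (5.80 against 10.32), the gastric tight junction gene Cldn18 (3.85 against 7.56), the pepsinogen gene Pgc (3.40 against 7.01), Anxa10 (3.07 against 7.82), Psca (2.30 against 5.65) and Mucl3 (3.47 against 9.91) were lower as well. The major urinary protein genes Mup19 (4.30 against 8.96), Mup22 (4.40 against 7.74) and Mup2 (4.06 against 7.13) completed the 15 with Igtp and Tgtp2. Of these 15 genes, those under the deletion-labelled array's median over named genes, 5.19, were dim there, so the size of their difference depends on that array's floor.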

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

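With 1 array per group, leaving out an array was impossible and a p-value could not be had. No paired analysis was possible because each group has 1 array. An alternative for linear values was not run, since the values are logs. Counting genes at 1.5-fold gave 813 higher and 848 lower, and at 3-fold 93 higher and 70 lower, as the threshold itself sets. Under the other alternatives the counts at 2-fold ran from 199 to 308 higher and from 179 to 269 lower, and setting the medians equal gave 221 higher and 252 lower against 246 and 228. Cnep1r1 stayed between -0.31 and -0.245. Of 306 list values, 290 kept their side of the random range and, where a list stood apart, its direction, 13 moved inside it with the same sign, 2 moved outside and 1 moved inside with the sign turned. With no filter on dim genes, dense core vesicle genes moved above the range (0.12), as did enteric neurons and glia (0.44), and host defence outside the Paneth granule turned from 0.30 to -0.035. The cause was not tested beyond the dim genes that this setting adds. The 13 were 7 for SREBP targets, 2 with no filter (tuft cells, fibroblasts) and 4 with both arrays filtered (interferon-stimulated genes, host defence, mast cells, smooth muscle). Primary list medians ran from 1.93 to 2.18 for granule products, 0.175 to 0.34 for Paneth regulators, -0.01 to 0.12 for dense core vesicles, -0.07 to 0.01 for ER stress and -0.14 to -0.055 for lipid synthesis. Among 89 named genes, 3 crossed 2-fold (Lgr5 at 0.96 and Nts at 0.99 with medians equal, Ifit3 at 1.00 with quantile normalization) and 0 reversed. Low signal limits genes near the array median, and 103 genes dim on both arrays also differed by 2-fold.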

Other observations

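All tests and lists in this part were chosen after the values were seen, apart from the lists named as fixed. The 4 gasdermin C genes, listed because 3 of them led the differences, had a median of 3.89, so that value is no independent evidence. Absorptive transporters of sugars, peptides and carboxylates, picked likewise, were lower by 2-fold or more for 9 of 14 kept genes, with a median of -1.79. Targets of YAP, a transcriptional co-activator that responds to tissue mechanics and injury, had a median of 0.89 over 10 kept genes, with Ccn1 and Edn1 among the 5 higher by 2-fold or more. That list was written after the values of 4 of the 5, Ccn1, Edn1, Thbs1 and Sox9, had been seen, and the 6 kept genes outside the fixed lists and the named genes had a median of 0.095, with Lats2 (-0.81) and Clu (-0.88) below 0. Edn1 (6.83 on the deletion-labelled array against 3.78), Thbs1 (5.26 against 3.99) and Amotl2 (5.36 against 4.15) were dim on the wild-type array.

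Genes past 2-fold lay next to each other more often than their number gives by chance. Runs of 3 or more neighbouring kept genes that differed by 2-fold in the same direction numbered 14, 7 higher and 7 lower, with 74 genes in all, while 100 shuffles of gene order gave a median of 0 runs and at most 2. The longest was a run of 22 Defa genes, followed by runs of 7 genes from H2-DMa to Tap2 and 7 trypsin genes. A run of 4 Mup genes had a median of -3.21. Outside these runs, the neighbours Alad (9.18 on the deletion-labelled array against 10.92) and Hdhd3 (7.20 against 9.71) were both lower. Members of such families can share probes, so a run is not a count of independent genes.

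Of a list of 10 distal small intestine genes, 7 were kept and 3 were dim on both arrays, where the labels name distal ileum. The 3 dim genes, of bile acid uptake and signalling, were Fabp6 (4.23 on the deletion-labelled array against 3.74), Slc10a2 (3.28 against 2.83) and Fgf15 (3.84 against 3.51). The bile acid exporter genes Slc51a (10.27 against 10.80) and Slc51b (10.82 against 12.21) lay well above the median of named genes on both arrays. Gata4, a transcription factor of the proximal small intestine, stood at 13.45 on both. Also dim on both arrays were the stomach genes Muc5ac (2.78 against 2.87) and Gast (2.85 against 4.15) and the acid-secreting parietal cell genes Atp4a (4.56 against 3.42), Atp4b (3.16 against 3.54) and Cblif (2.79 against 3.76). Of the parietal cell list 1 gene was kept, Aqp4 (0.46), which is also in the stem cell list.

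Paneth granule genes were higher on the deletion-labelled array, with a median of 2.16. A larger share of crypt base as the whole cause was taken to bring stem cell markers up by a like amount. Their median minus the granule median was -1.35, with each kept stem marker below the granule median. Whether these markers are as confined to the crypt base as granule genes was not tested, so the gap cannot exclude that cause. More Paneth cells, as against more granule transcript per cell, cannot be told apart here, because the median of Paneth regulators and markers outside the granule was 0.32, with Habp2 and Nupr1 near the granule genes and Xbp1 and Agr2 below 0. Xbp1 and Agr2 are shared with the ER stress and goblet cell lists, so their values need not follow Paneth cells. An exchange of the 2 labels stays open too, as Cnep1r1 differed by -0.27 and its probes may lie outside the deleted part. The genotype stays among the open explanations, untested with 1 array per group.

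Genes of other digestive organs differed in opposite directions, pancreatic ones higher and gastric ones lower on the deletion-labelled array. Pancreatic tissue in that preparation is a candidate explanation, since acinar genes outside the fixed list, among them Gp2 (1.74) and Cuzd1 (1.76), had a median of 1.12 over 10 kept genes (1, Dmbt1, had been seen before), though Spink1 lay at -0.45 and Paneth cells as a source were not excluded. Among these, Serpini2 (4.56) and Pdia2 (4.42) were dim on the wild-type array. Fixed acinar genes ran from 7.68 (Cela3b) to 17.04 (Amy2a5) on the wild-type array, above its median of 5.16. Such signal was thus on both arrays and differed in amount, so its presence is not particular to the deletion-labelled preparation. Stomach or pyloric tissue in the wild-type preparation cannot be told from other sources. Only 4 genes of a gastric list outside the 15 lowest were kept, at a median of -0.685. Vsig1 (-2.07) and Muc1 (-1.79) lay below 0, and Krt7 (1.52) and Gata5 (0.42) above. Krt7 (13.56) and Gata5 (10.12) were bright on the deletion-labelled array, where Gkn2 was dim (4.21), so their signal there need not be gastric. Gkn3, not in that list, was lower by 2-fold or more, in a run with Gkn1 and Gkn2. The stomach genes Muc5ac and Gast and the parietal cell genes Atp4a, Atp4b and Cblif were dim on both arrays. Whether pyloric tissue would carry them was not tested. A more proximal segment in the wild-type preparation stays open as well, with a distal list median 0.63 above the proximal one. The 7 distal genes ran from -1.39 (Slc51b) to 1.03 and the 9 proximal genes from -0.62 to 2.05 (Slc40a1). The 3 distal genes below 0 and the 4 proximal genes above 0 went against that account. Of the 4 distal genes above 0, Pyy (0.90) and Nts (1.03) are also enteroendocrine markers and Mep1a (0.97) and Cubn (0.63) are not. The distal genes Fabp6, Slc10a2 and Fgf15 were dim on both arrays and so are not in that median. The segment behind either array is thus not settled by these values. An effect of genotype on these genes was not tested and stays open.

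Genes inducible by interferon-γ were lower on the deletion-labelled array, 13 of 26 kept genes by 2-fold or more, with a median of -1.005 and with the peptide transporter genes Tap1 (10.68 against 13.56) and Tap2 (6.41 against 8.93) and the immunoproteasome gene Psmb9 (12.50 against 14.55) among the lowest. Another MHC haplotype as the whole cause is argued against by 20 kept genes that lie outside the MHC region, at a median of -0.85. Of the 20, 19 lay below 0 and Cxcl9 (0.80) above. The fixed lists or the named genes held 8 of them, and the other 12 had a median of -0.80. Those values bear only on a difference confined to the MHC region. A lower response to interferons of every type is argued against by the 22 kept genes of type I and III interferon, 19 of them above 0, at a median of 0.51. Of these, 16 had been seen in the fixed interferon list, and the 6 outside it were all above 0, with a median of 0.72. Among the 6, Ifit1bl1, Ifit3b and Oas1g belong to the IFIT and OAS families already seen above 0, and family members can share probes. Ifi27l2a (1.03) and Ifi27l2b (0.77) are of 1 family, and Cmpk2 stood at 0.15, so the 6 are little independent evidence. Fewer lymphocytes, a source of interferon-γ, remain a candidate explanation, as T cell and intraepithelial lymphocyte markers had a median of -0.77 in a list fixed before the data were examined. An effect of genotype stays open, untested with 1 array per group.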
